A study of Mus musculus with 8 samples.

How the data were processed

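Total RNA from 8 mouse hearts was extracted with Trizol and cleaned with a column and DNase, amplified to biotin-labelled RNA with an Ambion kit and hybridised to Illumina mouse bead arrays, per the labels' protocols. The deposited table holds a background-subtracted intensity for each of 25697 probes and array on a linear scale, called non-normalized per the file headers, and 28.2% to 31.5% of the values of an array lie below 0. Beside each intensity the deposited table gives a detection p-value, whose steps fit 798 negative controls per array. The scanner software, the slides and the way background was subtracted are not given in the sources used here. A second deposited table of intensity values had the same upper quartile (46.8) and maximum on all arrays and medians from 8.98 to 9.10, and kept the order of each array's own values (Spearman correlation 1, against at most 0.879 with another array), so it holds these intensities on a linear scale after quantile normalization, with no centring and no change of direction; it was used as an alternative.

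Groups and replicate numbers came from the sample descriptions, since the titles number the knockdown mice inconsistently. The labels name a separate mouse for each array. Groups share replicate numbers, but deviations from the group means correlated at 0.165, 0.005, -0.093 and -0.005 for mice of the same number, so the number was taken as a name and no pairing was used. Sex was not given, and Xist was detected on 1 array at most by any probe, so sex could not be read from the arrays. Median deposited signals per array were 8.40 to 10.1 and the 95th percentiles 502 to 742.

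Intensities were background-corrected by normexp with the background inferred from the detection p-values, offset by 16, quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, which left 9397. Differences were tested with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; intervals are 95% from the moderated spread. The offset draws folds of dim probes toward 1. A probe detected on no array of a group has only a bound there, and its fold is given as "at least": the mean of the other group against the mean, per array, of the higher of the lowest detected signal and the probe's own. A fold of a named gene whose lower group was detected on 1 to 3 arrays is also given, where printed, with each undetected value raised to its array's lowest detected signal, a step added after the results were seen. Bounds hold for 20 of the higher and 5 of the lower changed probes. Genes were named through the platform's annotation, updated by Entrez number with the RefSeq gene table, which named 23962 of the 23978 probes with 1 gene, the rest keeping the platform's name; 1719 probes had none and 0 had several. Genomic positions were used only to see which genes neighbour each other. Probe sequences were not used here, so cross-hybridisation between gene copies was not checked.

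For 30 gene lists, fixed before the data were examined as were the tests, the alternatives and the rule for named genes, 1 probe per gene (the highest mean) was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation kept 1 of 5 calls, and fry, which asks only whether a list's genes move and does not compare them with other genes, gave 4 lists moving in one direction and 21 with changes in either. The 4 were the ATF4 and hypertrophy lists, higher, and the complex I and contraction lists, lower. The fatty acid, leukocyte and atrial lists, called by camera, did not pass fry in one direction (fry adjusted p = 0.0863, 0.0607 and 0.144). Of the 707 entries of the lists 2 matched no gene. Named genes are Taz, the 15 largest increases and 15 largest decreases among changed genes whose groups did not overlap (probe with the smallest p), leaving out unnamed and clone-named genes, and up to 4 members per list that passed over the list alone, with the smallest p. Genes outside this rule were chosen after their values were seen.

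The test was tried on simulated arrays built from the wild-type means, with 200 changed probes in each of 20 simulations. With the residual spread of each probe it recovered 11.8% of changes of 0.5, 60.4% of changes of 1 and 89.6% of changes of 2 on the log2 scale, over a mean of 11019 tested probes. In these simulations 9.47% of the calls were false, above the nominal 5%, and 96.2% of the false calls lay below the median level of the tested probes; unchanged probes reached p under 0.001 at 1.70 times the nominal rate. Simulating with the moderated spread, tried after that excess was seen, gave 8.00% false calls, and a variance prior that follows intensity gave 5.93% and 6.21%. With no changed probe the test made 0 calls in 20 simulations with either spread. Calls of dim probes are therefore less certain than the adjusted p states. In simulations over 6889 genes with 1 list raised by 0.3, camera called that list 20 times out of 20 and a mean of 0.10 of the other 29. Genes were simulated there as independent with a common spread. The rate of false list calls where genes move together was therefore not measured.

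Alternatives covered no background correction, an offset of 50, median scaling, the quantile-normalized table, no filter and a stricter filter on dim probes, an intensity trend with robust variance, array weights, averaged probes of a gene, the replicate number as a block, wild-type hearts 3 and 4 alone (whose mouse numbers belong to the knockdown mice's series), the Xist level as a covariate and leaving out each heart in turn. Added after the data were seen were the Myl7 level as a covariate and leaving out the dimmest array of each group. A slide effect was not tested, as no slide was given.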

Results

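Gene expression was measured in the hearts of 8 mice at 2 months of age with Illumina bead arrays, 1 array per heart. In 4 mice, a doxycycline-induced short hairpin RNA was directed against Taz, the gene of tafazzin. Tafazzin is the mitochondrial enzyme that remodels the acyl chains of cardiolipin, the phospholipid of the inner mitochondrial membrane. Its loss in people causes Barth syndrome, a disease of heart and skeletal muscle. The other 4 mice were wild-type littermates on the C57BL/6J background. Both groups ate a diet with 625 mg/kg doxycycline, so that the drug itself was given to both. Each array held 25697 probes, of which 9571, 9601, 8935 and 9351 were detected in the wild-type hearts 1 to 4 and 10183, 9454, 10015 and 9027 in the knockdown hearts 1 to 4. Correlations of normalized log2 intensities over the tested probes were 0.980 to 0.985 between wild-type hearts, 0.983 to 0.990 between knockdown hearts and 0.971 to 0.981 between hearts of different groups. The number of arrays, 4 per group, limits the precision of every value.

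Taz was measured first, since it is the target of the hairpin. Its brighter probe (ILMN_2978525) had a deposited signal of 543 ± 69.3 (SD, n = 4) in wild-type hearts and 62.7 ± 7.73 (SD, n = 4) in knockdown hearts. The 4 knockdown signals lay between 53.3 and 69.9, all below the wild-type range of 477 to 639. After normalization Taz fell by 2.88 ± 0.117 (SE) on the log2 scale, a 7.34-fold decrease with a 95% interval of 6.14 to 8.77 (limma, Benjamini-Hochberg adjusted p = 1.11e-07), and 13.6% of the wild-type level was left. The dimmer probe (ILMN_2696855) was detected in 4 of 4 wild-type hearts and 1 of 4 knockdown hearts and fell by 1.56 ± 0.176 (SE, limma adjusted p = 0.000330), with a knockdown level at background. With undetected values raised to the lowest detected signal of their arrays the difference was -1.35. Every knockdown heart lay below every wild-type heart for both probes (exact two-sided permutation p = 0.0286 for each, the smallest that 70 assignments of the hearts can give).

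The comparison of knockdown with wild-type hearts asks which transcripts of the heart differ when Taz is lowered. The largest increases were in genes of amino acid supply and of the cell's response to amino acid shortage. Slc7a5, a transporter of large neutral amino acids, rose 12.6-fold (95% interval 9.98 to 15.9) and Chac1, which degrades glutathione, 10.8-fold (7.49 to 15.5). The transcription factor Atf5 rose 9.05-fold (7.06 to 11.6) and the secreted hormone Fgf21, detected in 1 of 4 wild-type hearts, 8.84-fold (6.56 to 11.9). Asns, which makes asparagine, and Mthfd2, an enzyme of the mitochondrial folate pathway, were detected in no wild-type heart and in all 4 knockdown hearts, at least 8.01-fold and at least 7.68-fold higher. The largest decreases were smaller. Ano10 fell 3.79-fold (2.81 to 5.12) and Lypd2, detected in 1 of 4 knockdown hearts, 3.73-fold (2.72 to 5.11). Acsl6, an enzyme that activates long-chain fatty acids, was detected in 2 of 4 knockdown hearts and fell 3.10-fold (2.48 to 3.87) and Ces1d, a carboxylesterase, 2.95-fold (2.29 to 3.80). The lower groups of Fgf21, Lypd2 and Acsl6 lay near background, so their folds are less certain than the intervals state. With each undetected value raised to the lowest detected signal of its array they were 7.65, 3.47 and 2.89. The other probe of Acsl6, dim in both groups, gave a 1.09-fold decrease (0.895 to 1.32) that did not pass. For the probes of the larger changes above the limma adjusted p lay between 1.97e-08 for Mthfd2 and 0.000247 for Lypd2. That all 4 hearts of one group lay above all 4 of the other was required by the rule that picked these genes.

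**Figure D1:**
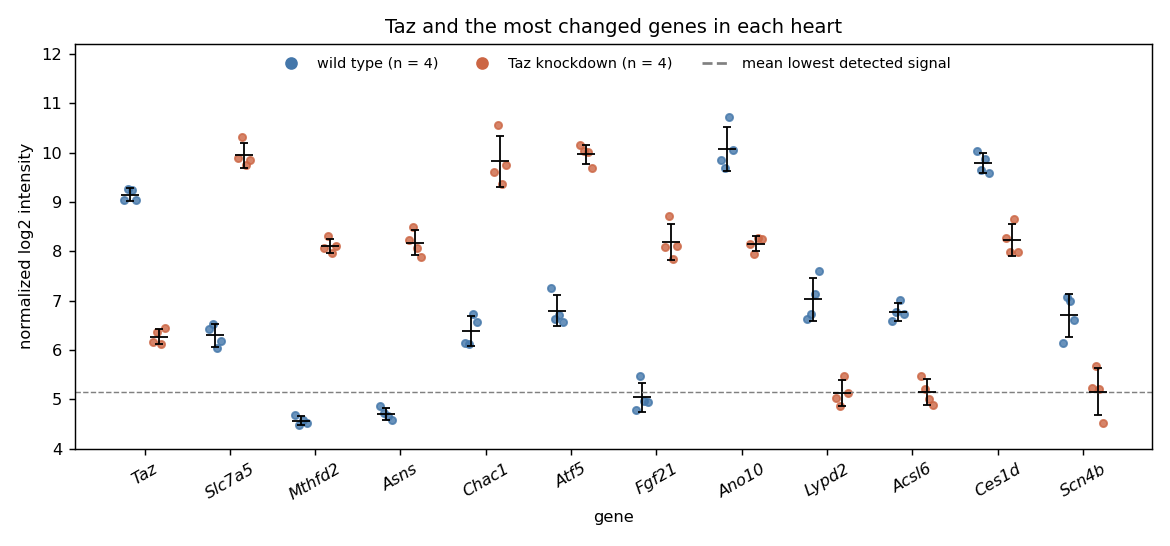
Normalized log2 intensity (vertical axis) of Taz, the 6 genes with the largest increase and the 5 with the largest decrease (horizontal axis) in each heart. Points are hearts, black marks the mean and SD of 4 hearts, and the dashed line the mean over arrays of the lowest signal that was detected; Mthfd2 and Asns lie below it in every wild-type heart, and Taz is lower in all 4 knockdown hearts.

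Of 9397 probes tested, which stood for 6889 genes and 522 probes without a gene name, 618 passed the limma Benjamini-Hochberg adjusted p of 0.05. Among them 321 were higher in the knockdown hearts (249 genes and 30 unnamed probes) and 297 were lower (255 genes and 14 unnamed probes). Changes over 2-fold were more often increases, with 78 probes (60 genes) higher and 24 probes (22 genes) lower. In 601 of the 618 the groups did not overlap, and among all tested probes 14.6% did not overlap where chance gives 2.86%. Of 170 changed genes with several tested probes, 44 changed by all of them in one direction and 126 had at least 1 probe that did not pass, while none passed in opposite directions. The counts moved by more than 1.5 times when some hearts were left out. The lower probes numbered 189 without wild-type heart 4, 191 without knockdown heart 1, 191 without knockdown heart 2 and 188 without knockdown heart 3, and the higher probes 197 without knockdown heart 2. They also fell to 209 higher and 165 lower against wild-type hearts 3 and 4 alone and to 173 and 142 without the dimmest array of each group. They were 145 and 106 with the Xist level as a covariate, and 73 and 26 with the level of the atrial gene Myl7 as a covariate. The Xist probe used was detected on 1 array, so its level does not adjust for sex. Myl7 itself differed by -0.71 on the log2 scale between the groups, so that covariate also takes up part of the group difference.

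Further large increases were those of Slc7a3, a transporter of cationic amino acids (at least 4.17-fold, detected in no wild-type heart), Aldh18a1, which starts proline synthesis (5.25-fold, 95% interval 3.88 to 7.10), and Phgdh, the first enzyme of serine synthesis (4.07-fold, 3.01 to 5.50). Aldh1l2, a mitochondrial folate enzyme, was at least 3.30-fold higher by a probe detected in no wild-type heart, and 2.55-fold (2.05 to 3.19) by its brighter probe, detected in all 8 hearts. The pseudokinase gene Trib3 rose 6.30-fold (4.73 to 8.40). Brca2, which acts in the repair of DNA breaks, rose 7.71-fold (5.90 to 10.1) and 2.92-fold (2.28 to 3.73) by its other probe. Tenm4, a transmembrane protein of cell contacts, rose at least 4.90-fold, Cat, the gene of catalase, at least 3.99-fold and Cdsn, known as an adhesion protein of the skin, 4.54-fold (3.11 to 6.63). Trib3 and Cdsn were detected in 1 of 4 wild-type hearts and Brca2 and Phgdh in 2 of 4, with means near background. With undetected values raised to the lowest detected signal the folds were 6.03 for Trib3, 4.04 for Cdsn, 7.05 for Brca2 and 3.79 for Phgdh. Among the decreases, Scn4b, a beta subunit of the voltage-gated sodium channel, fell 2.91-fold (1.98 to 4.28; 2.58-fold with the undetected value of 1 knockdown heart raised in the same way) and Dbh, which makes noradrenaline from dopamine, at least 2.08-fold, as it was detected in no knockdown heart. Cryba4 fell 2.76-fold, Lrg1 2.47-fold, the granzyme gene Gzmm 2.40-fold, Leprotl1 2.29-fold, Asph 2.26-fold and Art3 2.24-fold. The fall of Asph rests on 1 of its probes, and with its probes averaged it was -0.17 on the log2 scale (limma adjusted p = 0.302). Phkg1, the catalytic subunit of muscle phosphorylase kinase, fell 2.23-fold, Snai3 2.21-fold (2.20-fold with the undetected value raised) and the cytokine gene Il15 2.15-fold. Their limma adjusted p was between 1.84e-05 for Dbh and 0.00454 for Scn4b.

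The list of ATF4 targets and amino acid stress genes stood apart from the other 29 lists. Of its 27 measured members 23 rose, none fell and 4 did not pass; adjusted over the list alone 26 rose. The median log2 difference was 1.68 (camera adjusted p = 1.52e-40), and this was the only list past the threshold with an estimated correlation (adjusted p = 0.00944). Atf4 itself, the transcription factor that gives the list its name, rose by 1.68 on the log2 scale (limma adjusted p = 3.55e-05). The 4 members that did not pass over all probes were Ddit4 (0.47), Cebpb (0.42), Wars (0.30) and Vldlr (-0.06), which with Atf4 are named here after their values were seen. Only 15 members passed when probes were required to be detected with p under 0.01 on all 8 arrays, since several are dim or not detected in wild-type hearts.

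**Figure D2:**
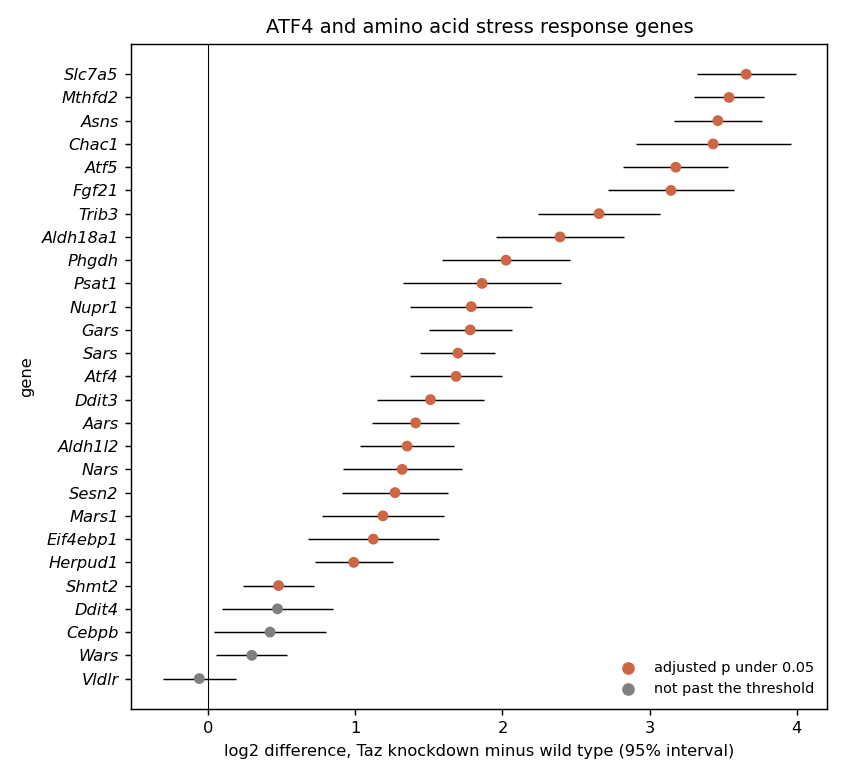
Difference in log2 intensity between knockdown and wild-type hearts (horizontal axis) for the 27 measured members of the ATF4 list (vertical axis), 1 probe per gene, with 95% intervals from 4 hearts per group. Of the members, 23 passed the adjusted p of 0.05, from Shmt2 at 0.48 to Slc7a5 at 3.66.

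Members of the respiratory chain differed little one by one. None of 29 complex I subunits passed, over all probes or adjusted over the list alone, but 26 of them had negative values and the median was -0.17 (camera adjusted p = 0.00114). The complex I call was lost with an estimated correlation (adjusted p = 0.646). Of 17 genes of complex IV subunits and assembly, Cox8a rose by 0.45 and 16 did not pass. Adjusted over the list alone 1 rose and 4 fell, among them Cox8b (-0.39), Cox7a1 (-0.35) and the assembly gene Cox17 (-0.33). The list did not pass (median -0.13, camera adjusted p = 0.448). None of 9 complex III genes (median -0.11, camera adjusted p = 0.272), 15 ATP synthase genes (median 0.02, adjusted p = 0.658) and 15 tricarboxylic acid cycle genes (median -0.12, adjusted p = 0.115) passed, over all probes or adjusted over the list alone. Without knockdown heart 1 the tricarboxylic acid cycle list passed (camera adjusted p = 0.0471).

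Genes of the cardiolipin and phospholipid pathway went both ways. Of 24 measured members, Lpin1, a phosphatidate phosphatase, fell by 0.73 ± 0.0954 (SE) on the log2 scale and Prelid1, a carrier of phosphatidic acid between mitochondrial membranes, rose by 0.42. Pemt, which methylates phosphatidylethanolamine, was detected in no wild-type heart and was at least 1.32-fold higher in knockdown hearts. The other 21 did not pass. Adjusted over the list alone Ptpmt1, a phosphatase of cardiolipin synthesis, also passed (0.41), giving 3 higher and 1 lower. The list as a whole did not pass (median -0.0042, mean 0.01, camera adjusted p = 0.917). Among 12 mitochondrial chaperones and proteases Hspa9 rose by 0.66 and Dnaja3 by 0.53 and 10 did not pass. The count adjusted over the list alone was also 2 (median 0.10, camera adjusted p = 0.441). Of 43 genes of the mitochondrial ribosome Mrpl49 fell by 0.46 and Mrps25 by 0.49, the latter named after its value was seen, and 41 did not pass. With p adjusted over the list alone 1 fell (median -0.03, adjusted p = 0.559). Of 20 genes of mitochondrial biogenesis and dynamics Tfam, which packages and transcribes mitochondrial DNA, fell by 0.87 and the nuclear receptor Esrrb by 0.39. The other 18 did not pass, and adjusted over the list alone the count was the same (median -0.01, adjusted p = 0.971). Pink1, a kinase that marks damaged mitochondria, fell by 0.39 among 16 genes of mitophagy and autophagy, and 15 did not pass. Adjusted over the list alone Sqstm1 also passed (0.41), and the list did not (median -0.00060, adjusted p = 0.971).

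Genes of fatty acid uptake and oxidation had mostly negative values, 24 of 26 members, with a median of -0.25 (camera adjusted p = 0.00114). The call was lost with an estimated correlation (adjusted p = 0.646) and without the dimmest array of each group, where the median was smaller in size (-0.16, camera adjusted p = 0.161). Acaa2, the last enzyme of the mitochondrial oxidation spiral, fell by 0.62 and Acot2, a mitochondrial thioesterase, rose by 1.03, while 24 did not pass. Adjusted over the list alone 7 fell and 1 rose, with Acot1 (-0.66) and Mlycd (-0.71) among the lower. The rise of Acot2 rests on a single probe, as its other probe stood at -0.12. Acot1 and Acot2 are close copies, and whether their probes tell them apart was not checked, so both values are uncertain. Of 23 glycolysis and glucose uptake genes, Pgam1 rose by 1.01, Pygb, a glycogen phosphorylase, fell by 0.79 and Pfkm, the muscle phosphofructokinase, fell by 0.36. The other 20 did not pass; adjusted over the list alone 2 rose, Pfkp (0.49) being the other, and 2 fell (median 0.06, camera adjusted p = 0.582). Among 14 genes of sterol and fatty acid synthesis Elovl1 rose by 0.42, 13 did not pass and the count adjusted over the list alone was 1 (median 0.02, camera adjusted p = 0.448).

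Several genes known to rise in the stressed or growing heart were higher. Of 14 members of the hypertrophy and fetal gene list, 5 rose, 1 fell and 8 did not pass. Acta1, skeletal muscle actin, rose 2.81-fold (95% interval 2.26 to 3.50), Uchl1, a ubiquitin hydrolase, 2.73-fold (2.09 to 3.56) and Ankrd1, a stretch-responsive repeat protein, 1.80-fold (1.45 to 2.23). Nppb (0.58 on the log2 scale) and Fhl1 (0.50), both named after their values were seen, rose as well. Mybpc2, a myosin-binding protein, fell by 0.68. Adjusted over the list alone 5 rose and 2 fell, and the list as a whole did not pass in camera (median 0.07, camera adjusted p = 0.115). By fry, which does not compare a list with other genes, it moved upward (fry adjusted p = 0.0160). Nppa, the other natriuretic peptide gene, stood at -0.29 (limma adjusted p = 0.449). Nppa is also a member of the atrial list, so its value does not speak for hypertrophy alone. Of 24 genes of contraction and calcium handling, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 0.72 and the potassium channel gene Kcnj3 by 0.61 (-0.41 with undetected values raised to the lowest detected signal, as it was detected in 1 of 4 knockdown hearts), and 22 did not pass, with the same count adjusted over the list alone (median -0.09, camera adjusted p = 0.115). By fry the contraction list moved downward (fry adjusted p = 0.0341). None of 22 extracellular matrix and fibrosis genes passed, over all probes or adjusted over the list alone (median 0.06, camera adjusted p = 0.748).

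Other stress programmes moved less than the ATF4 list. Of 22 antioxidant genes Cat, Hmox1, the stress-induced haem oxygenase (at least 1.29-fold), and Gclm, a subunit of the first enzyme of glutathione synthesis (at least 1.08-fold), were higher, all 3 detected in no wild-type heart. The other 19 did not pass, adjusted over the list alone Gss (0.58) made 4, and the list did not pass (median -0.01, mean 0.12, camera adjusted p = 0.448). Among 12 heat shock genes Hspb1 rose by 0.85, Hspb3 fell by 0.54 and 10 did not pass. With p adjusted over the list alone Cryab (0.59) also passed, giving 2 higher and 1 lower (median 0.02, camera adjusted p = 0.573). In the circadian list of 10 genes Tef fell by 1.03, Per1 rose by 0.80 and 8 did not pass, as when adjusted over the list alone (median -0.05, mean 0.10, camera adjusted p = 0.971). None of 8 immediate early genes passed over all probes, and adjusted over the list alone Egr1 (-0.57) and Ccn1 (-0.48) were lower (median -0.13, camera adjusted p = 0.448). None of 23 interferon response genes passed, over all probes or adjusted over the list alone (median -0.11, camera adjusted p = 0.431).

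Markers of cell types and tissues other than ventricular muscle were examined in the same hearts. All 8 atrial and conduction markers had negative values with a median of -0.54 (camera adjusted p = 0.00343). None passed over all probes, and adjusted over the list alone Myl7 (-0.71), Myl4 (-0.58), Mybphl (-0.80) and Sln (-0.75) were lower. The atrial call was lost with an estimated correlation (adjusted p = 0.646) and against wild-type hearts 3 and 4 alone (median -0.47, camera adjusted p = 0.0562). It was also lost with the level of Myl7, a member of the list, as a covariate (median 0.06, camera adjusted p = 0.818). Leukocyte and macrophage markers had a median of -0.27 (11 members, camera adjusted p = 0.00989). Lyz2, a lysozyme, fell by 0.48 and the class II antigen gene H2-Eb1 by 0.52, 9 did not pass, and the count adjusted over the list alone was also 2. That call was lost with an estimated correlation (adjusted p = 0.646) and without wild-type heart 2 (median -0.25, camera adjusted p = 0.0512). It was also lost against wild-type hearts 3 and 4 alone (median -0.28, camera adjusted p = 0.115) and with the Myl7 level as a covariate (median -0.23, camera adjusted p = 0.196). None of 14 endothelial markers (median 0.03, camera adjusted p = 0.849) and 10 fibroblast markers (median -0.11, adjusted p = 0.582) passed, over all probes or adjusted over the list alone. In each of 3 further lists 1 or 2 members passed over all probes and adjusted over the list alone. Acta2 rose by 0.85 among 10 smooth muscle and pericyte markers (median -0.04, mean 0.01, camera adjusted p = 0.971) and Adig by 1.51 among 7 adipocyte markers (median -0.28, adjusted p = 0.917; 0.23 without wild-type heart 4). Acta1, which the hypertrophy list also holds, rose and Casq1 fell by 0.81 among 4 skeletal muscle markers (median -0.25, mean 0.04, adjusted p = 0.748). Of 3 erythroid markers none passed over all probes, Slc4a1 (0.94) and Alas2 (0.59) passed adjusted over the list alone, and the list did not (median 0.59, camera adjusted p = 0.129) except without knockdown heart 2 (camera adjusted p = 0.00448). In camera the cardiolipin, biogenesis and antioxidant lists leaned upward with medians below 0, and the circadian, smooth muscle and skeletal muscle lists leaned downward with means above 0, none of them past the threshold. The medians of 13 of the 25 lists that did not pass changed sign without at least 1 heart, the adipocyte list and 12 whose medians were at most 0.06 in size.

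In 11 lists no member passed over all probes. Their members with an unadjusted limma p under 0.05 numbered 10 of 29 for complex I, 1 of 9 for complex III, 3 of 15 for ATP synthase and 2 of 15 for the tricarboxylic acid cycle. They numbered 2 of 22 for the extracellular matrix, 2 of 8 for immediate early genes, 3 of 23 for the interferon response, 5 of 8 for atrial, 0 of 14 for endothelial, 2 of 10 for fibroblast and 2 of 3 for erythroid markers.

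Of 78 named genes past the threshold, 57 passed again without each single heart. The other 21 missed it in at least 1 of these fits, each of which also has fewer hearts. Gclm, Prelid1, Pfkm and Esrrb missed it whichever heart was left out, with a highest limma adjusted p of 0.132, 0.103, 0.126 and 0.108. Another 8 passed without 1 heart alone and missed it without any of the other 7. That heart was wild-type heart 1 for Elovl1 (highest limma adjusted p 0.127) and Gstp1, a glutathione transferase (0.0924), wild-type heart 2 for Rars2, a mitochondrial transfer RNA synthetase (0.126), and wild-type heart 3 for Lyz2 (0.120). It was wild-type heart 4 for Cox8a (0.122), knockdown heart 2 for Pink1 (0.117) and Mrps25 (0.107), and knockdown heart 3 for H2-Eb1 (0.128). Gstp1 and Rars2 were named after their values were seen. Hspb3 missed it without wild-type heart 2 or 3 or knockdown heart 1, 2 or 3 (0.0737 at most), and Acaa2 without wild-type heart 2, 3 or 4 or knockdown heart 2 or 3 (0.0943). Dnaja3 missed it without wild-type heart 2 or 4 or knockdown heart 1, 2 or 3 (0.0764), and Nppb without wild-type heart 3 or 4 or knockdown heart 1, 3 or 4 (0.0606). Adig missed it without wild-type heart 1 or 2 or knockdown heart 2 or 3 (0.0720), Kcnj3 without wild-type heart 1 or 2 or knockdown heart 3 or 4 (0.0742) and Pgam1 without knockdown heart 2, 3 or 4 (0.0619). Mrpl49 missed it without wild-type heart 4 (0.0547) or knockdown heart 1 (0.0531), and Pygb without wild-type heart 4 (0.0546).

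With the probes of a gene averaged, 11 of the 78 missed the threshold. The log2 difference became -0.17 for Asph, -0.43 for Tef, 0.46 for Acot2, -0.41 for Acaa2, -0.36 for Tfam, -0.24 for Mrpl49, -0.37 for Pink1, 0.22 for Elovl1, -0.08 for Gstp1, -0.38 for Mrps25 and 0.33 for Rars2, with a limma adjusted p from 0.0535 (Pink1) to 0.708 (Gstp1). Of the 30 genes with the largest changes, 8 missed the threshold under an alternative. Without background correction, where signals at or below 0 took the lowest positive value, these were Asns (limma adjusted p = 0.173), Aldh1l2 (0.227), Dbh (0.262) and Scn4b (0.462). Their log2 differences there, 10.95, 12.56, -8.85 and -6.91, were larger in size than in the main fit. With the Myl7 level as a covariate the genes that missed it were Lypd2 (limma adjusted p = 0.0516), Il15 (0.0527), Scn4b (0.144) and Snai3 (0.181). Their log2 differences there were -1.64, -1.05, -1.55 and -0.82. With probes averaged it was Asph. In the lower group, Snai3, Adig, Per1, Slc4a1, Mlycd, Pgam1, Mybpc2, Tfam and Casq1 were detected in 3 of 4 hearts.

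**Figure D3:**
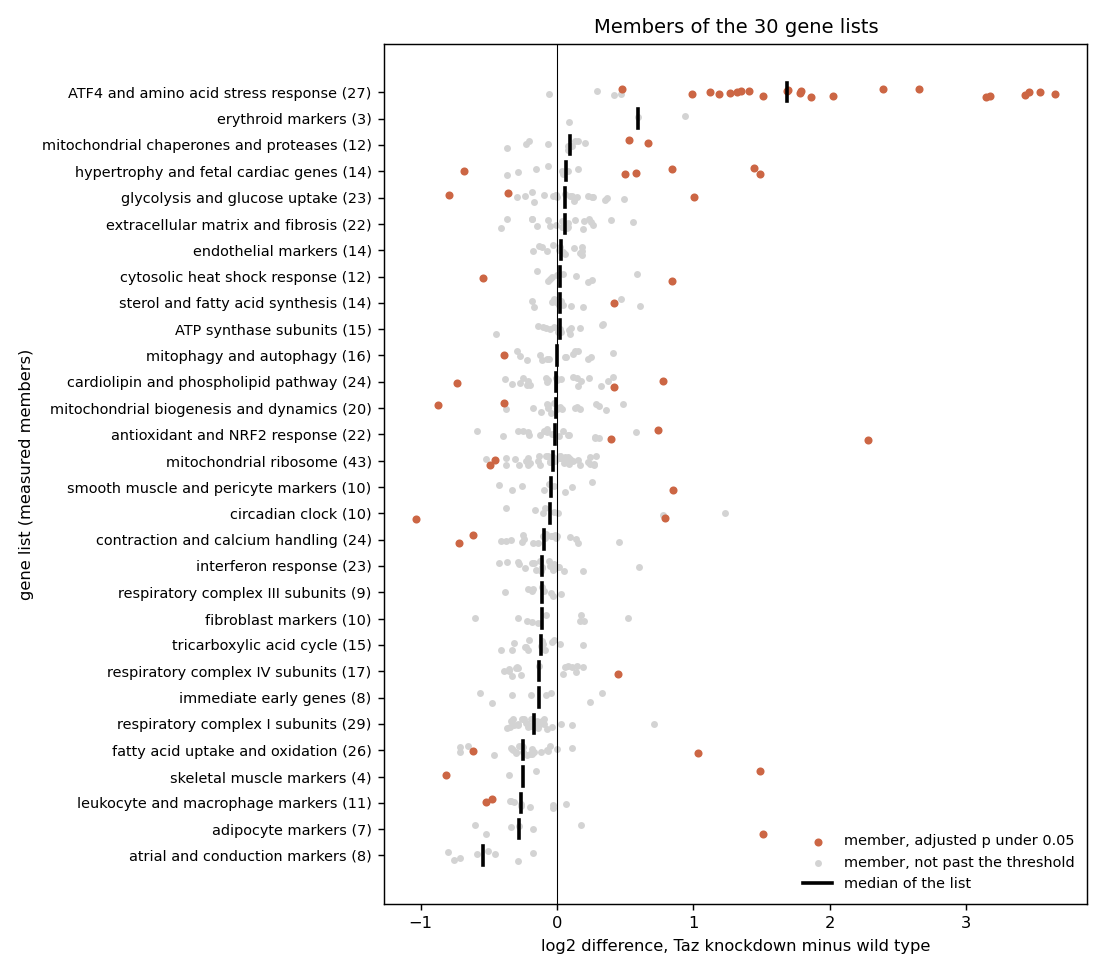
Difference in log2 intensity between knockdown and wild-type hearts (horizontal axis) of each measured member of the 30 gene lists (vertical axis, with the number of measured members). Coloured points passed the adjusted p of 0.05 and black bars are medians of the lists; the median of the ATF4 list lies at 1.68 and that of the atrial list at -0.54.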

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

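The tests on neighbouring positions, on the correlation of atrial markers and on marker lists of other cells were chosen after the results were seen, as was the Myl7 covariate; the others were fixed before. Among 212 groups of 4 hearts 10 held a heart whose gap to its neighbour, as a share of the group's range, exceeded Dixon's critical value. Chance alone flags about 10.6 of 212. Wild-type heart 3 had the lowest 95th percentile of signal (502, against 636 to 657 in the other wild-type hearts) and the highest Trib3 (5.45 on the log2 scale, against 5.03 to 5.09). Wild-type heart 1 was lowest for Acot2 (6.77, others 7.27 to 7.34), Eprs (7.38, others 7.69 to 7.71) and Gstp1 (12.09, others 12.23 to 12.26). Knockdown heart 3 was lowest for Mybphl (9.03, others 9.56 to 9.66), N4bp2l1 (7.16, others 7.58 to 7.61) and Atf4 (7.67, others 8.17 to 8.25). Knockdown heart 2 was lowest for Nppb (12.31, others 12.70 to 12.75) and knockdown heart 4 for Cryab (11.06, others 11.53 to 11.59).

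The real grouping gave 618 changed probes, and the highest other split of the 8 arrays gave 1. The only split of the 35 that gave as many was the real grouping itself. All other splits mix the groups, which widens the spread within each side. Their low counts therefore do not measure what chance gives, and this test alone does not exclude chance. For gene lists past the threshold, 11 of the 35 splits, the real grouping among them, gave at least its 5, and the highest other split gave 7. Splits that keep 3 hearts of one group together hold part of the real difference, so these are not counts under chance alone. Splits with 2 hearts of each group on each side also reached 5 lists, so chance cannot be excluded for that number. The 10 Mb window with the most changed genes held 14 of 504, or 2.78%. A window of that size covers a small part of the genome and could hardly hold most of the changed genes. Changes that a stretch of another strain's genome beside the transgene causes elsewhere would not show there. Whether such a stretch contributed therefore stays open.

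The rise of the ATF4 list was weighed against a pair of other differences between the groups. Wild-type mice 1 and 2 carry numbers of another series, but against wild-type hearts 3 and 4 alone the list's median rise was 94.3% of that against all 4. The lower atrial markers of the knockdown hearts do not account for it either, as the median rise was 1.81 on the log2 scale with the Myl7 level as a covariate, against 1.68 without it. Sex and the litter of each single mouse were not given and stay open. So does an effect of the hairpin itself apart from the loss of Taz, since the design has no control hairpin. The lowering of Taz remains a candidate explanation.

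The fall of the atrial markers is consistent with a smaller share of atrial tissue in the knockdown samples. Of the 8 measured markers only the 4 that passed over the list alone, Myl7, Myl4, Sln and Mybphl, were used here. Their deviations from their group means correlated at a mean of 0.934 (0.868 to 0.991 over 6 pairs of markers, Spearman 0.833 to 1). The two-sided permutation p was at most 0.00511 and 0.0154, the same after adjustment over the pairs. These permutations moved deviations across both groups, although each was centred on its own group and the spreads differ. The p-values are therefore approximate and may be too small. Leaving out the 2 hearts farthest from the median gave 0.910 to 0.991. Markers of a tissue present in varying amounts would do this. A change of these genes within the same tissue would also move them together, so a lower expression in the knockdown atria stays open. The dissection is not described in the labels.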

How the results depend on the processing

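The Myl7 covariate and the omission of the dimmest arrays were chosen after the results were seen. Taz kept its direction and call under all 22 alternatives (-3.16 to -2.22 on the log2 scale; -2.94 to -2.83 leaving out 1 heart), as did the ATF4 list (median 1.35 to 1.83, highest adjusted p 3.42e-24) and the complex I list under camera's preset correlation. Leaving out 1 heart gave 197 to 264 higher probes (155 to 208 genes), 188 to 261 lower probes (159 to 221 genes), 4 to 6 lists and 22 or 23 ATF4 members, and fewer hearts alone lower such counts. Higher and lower probes numbered 207 and 194 (168 lower genes) without background correction and 209 and 165 (140 lower genes, 3 lists) against wild-type hearts 3 and 4. Lower probes numbered 451 with an offset of 50 and 477 (407 genes) with an intensity trend and robust variance, where 464 were higher. With the level of Xist, whose probe was detected on 1 array, as a covariate 145 (115 genes) were higher and 106 (91) lower. Without the dimmest arrays 173 (136 genes) were higher and 142 (121) lower, and with the Myl7 covariate 73 (60) and 26 (24). Under that covariate the adipocyte list turned to a median of 0.69 (camera adjusted p = 0.00564; without wild-type heart 4 it was 0.23), the atrial list to 0.0560, Mybphl to 0.0882, Sln to 0.0650 and Nppa to 0.324; Myl7 belongs to the atrial list and correlated with Mybphl and Sln, so the covariate removes their fall whatever its cause. Nppa is a member of the atrial list too, but its correlation with Myl7 was not computed. For Nppa and the adipocyte list the cause was not tested. Lists past the threshold numbered 8 without a filter (complex III, tricarboxylic acid cycle and contraction also passed; so did hypertrophy under the strict filter, contraction with averaged probes, and hypertrophy, sterol synthesis and the tricarboxylic acid cycle under the Myl7 covariate), 1 with an estimated correlation and 21 by fry's mixed test, and the strict filter left 15 ATF4 members, as it tests fewer genes. The replicate block gave 215 higher probes and 184 lower (157 genes), with 5 lists; the numbers share no more than a name, since 3 of 4 same-number correlations lay below 0.1. For counts not explained above the cause was not tested. No alternative reversed any of the 78 named genes that had passed, and 39 to 77 of them passed again where all 78 were tested. Probes near background limit the rest: 34.8% to 39.6% of probes were detected per array.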

Other observations

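The tests in this part on marker lists of other cells, on neighbouring genes, on the ribosomes and on the synthetases were chosen after the results were seen. The gene sets here were formed then too, except the mitochondrial ribosome and the marker lists, which were fixed before. Adjustment over 5 sets does not account for that choice. Genes of the cytosolic ribosome were slightly higher in the knockdown hearts: of 50 measured ribosomal protein genes 47 had positive values, 11 rose and none fell, with a median of 0.34 on the log2 scale (camera p adjusted over 5 such sets = 2.93e-16, a call lost with an estimated correlation, adjusted p = 0.0555). The mitochondrial ribosome had a median of -0.03, and the difference between the means of these sets was 0.39 larger in knockdown hearts (SD 0.07 in wild-type and 0.05 in knockdown hearts, exact two-sided permutation p = 0.0286, the smallest possible). Rpl3 rose by 1.05 (limma adjusted p = 0.00134), while its muscle-specific paralog Rpl3l fell by 1.00 (limma adjusted p = 0.000199). Among 15 glutathione transferases 6 fell and 1 rose, with a median of -0.39 (camera adjusted p = 9.77e-05, also lost with an estimated correlation, adjusted p = 0.0555). Mgst1 fell by 0.88 and Gstk1 by 0.68, Gsto1 rose by 0.69, and Gstp1 fell by 0.40 by one probe while another stood at 0.24. Cdkn1a, an inhibitor of the cell cycle, rose by 1.87 (limma adjusted p = 2.19e-06).

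For the rise of the ribosomal protein genes 4 technical explanations were tested. Their brightness does not account for it, as none of 10000 lists of other genes matched on level (0%) had a median as high, the highest being 0.09. The choice among the normalizations tried does not either, since under 4 other background and scaling choices the median stayed at least 0.33 above that of all tested genes. Each of them makes the arrays equal in distribution or in median, so an error that they share stays open. A larger share of all cells other than myocytes would raise the markers of each kind, but leukocyte markers had a median of -0.27, and their array means fell by 0.25 (SD 0.10 in each group, exact two-sided permutation p = 0.0286, the smallest possible). The medians of the marker lists were known when this test was chosen. The leukocyte call itself was lost under several alternatives, so it speaks only weakly against such a larger share. A larger share of a single kind stays open. Medians were 0.03 for endothelial, -0.11 for fibroblast and -0.04 for smooth muscle markers, and all 3 erythroid markers were higher, with a median of 0.59 (exact two-sided permutation p of the array means = 0.114). Per array, the ribosomal mean rose over the endothelial, fibroblast and smooth muscle means by 0.31, 0.38 and 0.33 (exact two-sided permutation p = 0.143, 0.0857 and 0.0571). Against leukocyte markers the difference was 0.59 (exact p = 0.0286) and against erythroid markers -0.20 (exact p = 0.486). A higher expression of these genes with lowered Taz stays as a hypothesis, and cross-hybridisation with ribosomal pseudogenes was not tested.

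Transfer RNA synthetases of the cytosol may have risen apart from those of mitochondria. Of 9 cytosolic synthetase genes outside the ATF4 list 5 rose (median 0.56, Eprs 1.55 and Iars 1.25; camera adjusted p = 3.45e-07, a call lost with an estimated correlation, adjusted p = 0.0555), and of 10 mitochondrial ones 1 rose (median -0.10, Rars2 0.41). Kars (0.56), counted as cytosolic, encodes the enzyme of both compartments and so does not tell them apart. The difference between the set means was 0.59 larger in knockdown hearts (exact two-sided permutation p = 0.0286, the smallest possible). Brca2 and its neighbour N4bp2l1 (1.84) both rose, and it was asked whether adjacent genes changed together more widely: 18 adjacent pairs changed in one direction, the median of 10000 permutations was also 18 (p = 0.559), so this was not found.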
